A study of Mus musculus with 6 samples.

How the data were processed

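RNA-seq was carried out on 6 samples of mouse skin: 3 from untreated control mice and 3 from mice given osimertinib for 42 days. Osimertinib is an inhibitor of the epidermal growth factor receptor (EGFR) used against lung cancer. Groups and replicate numbers were taken from the sample titles. Nothing in the labels states that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

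Per the labels' protocols, polyadenylated RNA was selected, fragmented and made into libraries in which the second cDNA strand was marked with dUTP and removed, with unique molecular identifiers in the adapters, and sequenced in pairs on an Illumina NovaSeq. Per the submitters' processing notes, cutadapt 1.9 was used and the genome build was GRCm38. The aligner, the counting tool, the gene annotation, the use of strand in counting and the use of the molecular identifiers are not given in the sources used here. Reads of genes on opposite strands, and reads of near-identical paralogs such as the keratin-associated protein, Sprr2 and MHC class I genes, may therefore have been divided between genes in an unknown way. A group of mitochondrial-like genes that includes Gm28661 and Gm28437 held between 1.11% and 2.49% of each library's count. The deposited table holds whole-number counts per gene, not normalized, and beside them FPKM values per gene, which the authors computed (fragments scaled by gene length and library size, per the file headers). Of 33308 genes in the table, 33211 had an Ensembl identifier in GENCODE mouse release 21, and 99.5% of these had the same start. Coordinates are given as in the deposited table, on GRCm38. A further 6 columns of values in the table match no sample of the series and were not used.

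Library totals ran from 54112624 to 60719064 counts. In a library of this size, a count of 0 allows up to 3 counts, which is a level of 0.0494 to 0.0554 CPM before TMM scaling. Such limits cover counting error only.

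Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 13498 in all. The design written before the data were examined named limma on log2(FPKM + 1), and edgeR in its place if the table held raw counts. Since it does, the main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling, no covariate, a two-sided p and Benjamini-Hochberg adjustment, with a threshold of 0.05. Fold changes are osimertinib over control, and their standard errors (SE) were obtained as the log2 fold change divided by the square root of the F statistic. Levels are counts scaled to library size with TMM factors (CPM), given as mean ± SD over 3 libraries.

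A set of 55 gene lists covering skin and hair programmes, signalling, immunity and the other cell types that a skin piece can hold was fixed before the data were examined. Of their 931 genes, 915 were matched to the table, and the 53 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, correlation between genes preset at 0.01, trended variance), with Benjamini-Hochberg adjustment over the lists. A list score is the mean over members of log2 CPM minus the gene's mean over the 6 libraries. Camera was repeated with a correlation estimated for each list. Annotated KEGG pathways with 10 to 300 tested genes were tested with camera after the data had been seen.

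Genes were named by a rule fixed before the data were examined. It takes the genes past the threshold with separated groups and the largest changes or, where fewer than 5 pass in a direction, the 10 with the smallest p in that direction. It also takes 10 EGFR family genes and up to 4 members with the smallest p of each list described. Names made of Gm or LOC and a number, or ending in Rik, were left out of the first part. Some genes that the rule takes are not reported here.

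The tests were first run on simulated counts with the means, library sizes and spread of these libraries and with 67, 67 and 66 genes changed 2-fold, 4-fold and 8-fold. In this simulation of osimertinib against control, over 13497 genes, edgeR recovered 0% of genes changed 2-fold, 35.8% of those changed 4-fold and 77.3% of those changed 8-fold, with 6 false calls. DESeq2 recovered 10.4%, 89.6% and 98.5% with 59 false calls. Camera called the 1 raised list of 20 genes and 0 of 20 unchanged lists. Simulated counts were drawn for each gene independently, so these lists had no correlation between genes. In the data the estimated correlation reached values such as 0.888 for hair keratin-associated proteins, against the preset 0.01. The simulation therefore cannot show how often camera falsely calls lists of correlated genes. In a comparison of single values over 3 against 3 samples, the smallest exact p is 0.1.

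Alternatives planned before the data were examined were DESeq2 1.42.0, limma on log2 FPKM with smaller pseudocounts, other filters on low values, other scalings, other variance moderation, library weights, the replicate number as a block, and leaving out each library. Alternatives added after the data were seen were limma on log2(FPKM + 1) beside the count test, and the skeletal muscle score as a covariate, with and without control 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.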

Results

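The transcriptome of mouse skin was measured by RNA-seq in 3 skin samples from untreated mice and 3 from mice given osimertinib for 42 days. The series design names osimertinib-induced skin problems as its subject, and the comparison asks which genes differed in treated skin. Total counts ran from 54112624 in control 1 to 57174797 in control 3, and from 59877553 in osimertinib 1 to 60719064 in osimertinib 3.

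Skin from osimertinib-treated mice had higher levels of transcripts of the growing hair follicle than control skin. Hair keratin-associated proteins, hair shaft keratins, the inner root sheath, matrix regulators such as Wnt10b and Msx2, pigment cell genes and proliferation genes were all higher as lists. A list of hair follicle stem cell genes, led by Fgf18, Krt15 and Cd34, was lower, as were interferon-response, basal keratinocyte and glucocorticoid-response lists. Egfr itself differed by 0.11 ± 0.25 on the log2 scale (SE, n = 3 per group), within its error. No single gene passed the adjusted threshold of edgeR, so these differences rest on lists of genes, of which camera called 22 of 53, 9 as higher and 13 as lower, and with an estimated correlation 0 of 53 were called.

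The libraries differed in how much muscle they held. Genes of the skeletal muscle list took 5.22%, 15.4% and 0.0381% of the count in controls 1, 2 and 3, and 8.16%, 5.04% and 8.02% in osimertinib samples 1, 2 and 3. The adipocyte list took 0.449%, 0.887% and 0.0946% in the controls and 0.302%, 0.302% and 0.509% in the treated samples. Camera called the skeletal muscle list as higher (adjusted p = 0.0109, and adjusted p = 0.909 with an estimated correlation), although the median log2 fold change of its 24 genes was −0.30 and their mean −0.14, with 7 higher and 17 lower. The mean of the list score, which averages log values of each library, was 2.08 higher in treated skin, and control 3 had the lowest score, −6.10. The median turned positive with limma on log2 FPKM (2.07, 2.17 and 2.21 at pseudocounts of 1, 0.1 and 0.01), with quantile normalization (2.11), with the replicate block (1.14) and without control 2 (1.42). It was −0.57 without control 1 and −0.0763 without osimertinib 2. The call was lost without control 3 (median −0.91, adjusted p = 0.122). None of its members passed on its own, Myh2 being nearest with 1.32 ± 1.40 (SE, n = 3 per group). The first principal component of the 6 libraries held 55.8% of the variance and placed control 3 at −125 against −48.0 to 55.0 for the other libraries.

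**Figure D1:**
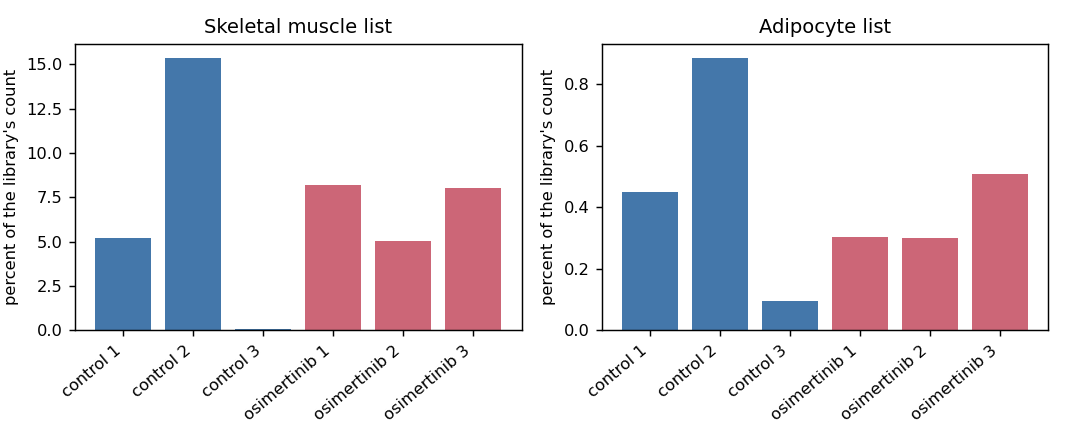
Bars give the percent of each library's total count in the genes of the skeletal muscle list (left) and of the adipocyte list (right), for 3 control (blue) and 3 osimertinib (red) libraries. Control 2 holds the largest muscle share, 15.4%, and control 3 the smallest, 0.0381%.

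Hair structural genes were higher in treated skin, by widely different amounts. Without Krt80, an epithelial keratin, the hair shaft keratins and keratin-associated proteins took 0.00468%, 0.0312% and 0.00574% of the count in controls 1, 2 and 3, and 0.143%, 0.955% and 0.0728% in osimertinib samples 1, 2 and 3. With Krt80, which made up most of the sum in controls 1 and 3, the shares were 0.0641%, 0.0437% and 0.0518%, and 0.161%, 0.966% and 0.0761%. All 42 tested keratin-associated proteins, which cross-link keratins in the hair shaft, had a positive log2 fold change, with a median of 5.13, the same with genes at 0 in all controls set to their bound over the group, and in 31 of them every treated sample lay above every control (adjusted p = 7.48e-21 by camera, and adjusted p = 0.664 with an estimated correlation). For example, Krtap4-1 averaged 0.179 ± 0.152 CPM in controls and 12.5 ± 17.2 CPM in treated skin (log2 fold change 6.14 ± 1.44, SE). Among 14 hair shaft keratins 13 were higher (median 4.59, adjusted p = 1.05e-06, and adjusted p = 0.664 with an estimated correlation), such as Krt36 at 4.93 ± 1.38 and Krt31 at 4.45 ± 1.71. The exception was Krt80, whose log2 fold change was −1.83 ± 0.74. Among 15 inner root sheath genes 13 were higher (median 4.36, adjusted p = 1.05e-06, and adjusted p = 0.664 with an estimated correlation), including trichohyalin (Tchh, 4.21 ± 1.30) and Krt26 (5.44 ± 1.84). In edgeR no member of these lists passed adjusted over the list alone or over all genes, while DESeq2 called 2, 1 and 2 members over all genes. Control 2 was nearest to the treated samples, with a hair shaft keratin score of 0.81 against 0.95 in osimertinib 3. Krt35 was at 62.7 CPM there, at 0.329 and 0.299 in controls 1 and 3, and at 351 to 1262 in treated skin. Without control 2 the 3 medians became 11.68, 10.13 and 8.79, and without osimertinib 2 they became 2.68, 2.41 and 2.42, in the order given here. The keratin-associated median was 2.50 with limma on log2(FPKM + 1) and 2.31 with quantile normalization, and the inner root sheath median was 2.80 with the latter. With the muscle score as a covariate and control 3 left out, the hair shaft keratin and inner root sheath medians were 7.25 and 6.77.

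Regulators of follicle growth followed the same direction with smaller spread. Of 17 genes of the hair matrix and follicle growth list, 16 were higher, with a median log2 fold change of 2.58 (adjusted p = 1.69e-11 by camera, and adjusted p = 0.664 with an estimated correlation), or 1.53 without osimertinib 2 and 1.66 with quantile normalization. Adjusted over the list alone, 11 passed in edgeR, against 0 over all genes tested, where DESeq2 called 11. Wnt5a, a secreted Wnt ligand (chromosome 14, 28504750 to 28527448), was at 17.6 ± 1.68 CPM in controls and 53 ± 7.10 in treated skin, a log2 fold change of 1.59 ± 0.17. Wnt10b, a Wnt ligand of the early growing follicle (chromosome 15, 98770712 to 98778150), went from 3.50 ± 1.78 to 42.0 ± 15.7 CPM (3.58 ± 0.47). The transcription factors Msx2 and Hoxc13, which act in the hair matrix, differed by 3.84 ± 0.58 and 2.68 ± 0.43. In all 4 genes each treated sample lay above each control.

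Pigment cell and proliferation lists were also higher. Of the 12 melanocyte genes listed, 7 passed the filter on mean FPKM and were tested. Of 7 melanocyte genes 6 were higher, each with separated groups and each passing in edgeR adjusted over the list alone, against 0 in edgeR and 6 in DESeq2 over all genes (list median 3.57, adjusted p = 1.05e-06, and adjusted p = 0.664 with an estimated correlation). With quantile normalization that median was 2.35. Slc24a5, a melanosomal exchanger, had a log2 fold change of 5.01 ± 0.73, the melanosome matrix protein Pmel 3.22 ± 0.48, and the melanin synthesis enzyme Dct 3.70 ± 0.69. Mitf, the melanocyte transcription factor, was the exception at −0.70 ± 0.74. All 26 proliferation genes were higher, with a median of 0.93 (adjusted p = 3.06e-13, and adjusted p = 0.664 with an estimated correlation), and 5 passed in edgeR adjusted over the list alone, against 0 in edgeR and 6 in DESeq2 over all genes. The 5 included the replication helicase subunits Mcm2 (1.28 ± 0.19) and Mcm3 (1.39 ± 0.28) and cyclin E1 (Ccne1, 1.95 ± 0.36). Control 3, which held little muscle, had the highest proliferation score among controls, 0.18 against −0.88 and −0.92, and without it the median became 1.44, or 1.40 with the muscle score as a covariate as well.

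**Figure D2:**
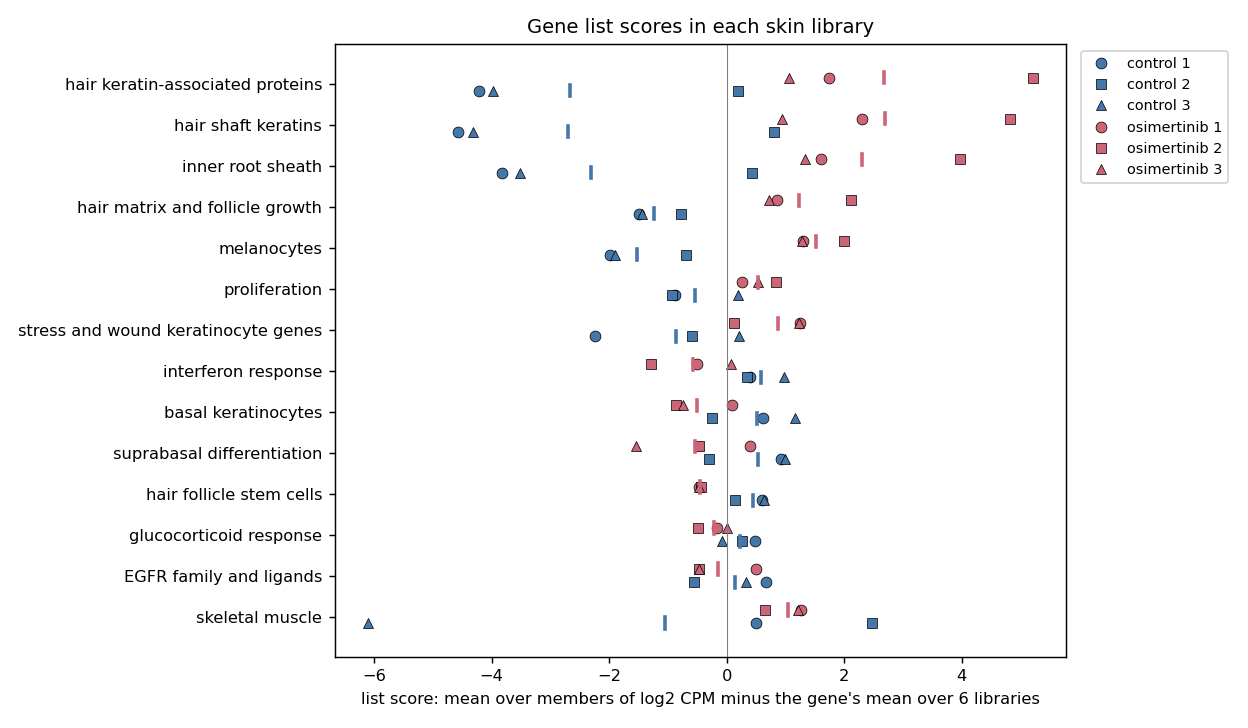
Each point is the score of a gene list (vertical axis) in a skin library, on a log2 scale relative to the mean of the 6 libraries (horizontal axis); vertical bars mark group means, blue for control and red for osimertinib. In the hair matrix list the treated libraries lie between 0.73 and 2.12 and the controls between −1.49 and −0.78, whereas control 2 stands apart from the other controls in the hair shaft keratins (0.81) and control 3 in skeletal muscle (−6.10).

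Follicle stem cell genes and a list of Wnt and BMP inhibitors were lower. In the list of hair follicle stem cell genes 11 of 13 were lower, with a median log2 fold change of −0.51 (adjusted p = 0.00121 by camera, and adjusted p = 0.664 with an estimated correlation), or −0.31 without control 3, −0.34 with limma on log2(FPKM + 1) and −0.33 with the muscle covariate, and 3 passed in edgeR adjusted over the list alone, against 0 in edgeR and 3 in DESeq2 over all genes. Fgf18, a growth factor that holds follicles in rest (chromosome 11, 33117430 to 33147400), was at 20.9 ± 9.34 CPM in controls and 1.14 ± 0.37 in treated skin, 18.3-fold lower (log2 fold change −4.20 ± 0.50). The stem cell markers Krt15 and Cd34 differed by −2.56 ± 0.68 and −1.13 ± 0.32. A list of Wnt and BMP inhibitors of hair growth, which also holds Fgf18, had 10 of 13 genes lower (median −0.43, adjusted p = 0.0109, and adjusted p = 0.664 with an estimated correlation), and 4 lower and 1 higher passed in edgeR adjusted over the list alone, against 0 over all genes, where DESeq2 called 4 lower and 1 higher. Its members did not all act in the sense of its name: the BMP antagonists Nog (−1.47 ± 0.31) and Grem1 (−2.21 ± 0.48) were lower, and the Wnt antagonist Wif1 was higher (2.63 ± 0.36). This list did not pass without osimertinib 1 (median −0.39, adjusted p = 0.0536) or with a mean FPKM of at least 5 (median −0.51, adjusted p = 0.13), while its median was −0.68 without control 2, −0.75 without osimertinib 3, and −0.24 and −0.28 with limma at pseudocounts of 1 and 0.1.

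Epidermal lists were lower, except for stress genes. All 12 basal keratinocyte genes were lower (median −1.09, adjusted p = 0.000432 by camera, and adjusted p = 0.867 with an estimated correlation), or by −0.71 without control 3 or with the muscle covariate, and 1 passed in edgeR adjusted over the list alone, against 0 in edgeR and 2 in DESeq2 over all genes. It was dystonin (Dst), a linker of keratin filaments to hemidesmosomes, at −1.87 ± 0.40. Suprabasal differentiation (11 of 14 lower, median −1.21), cornified envelope (22 of 30 lower, median −0.77), barrier lipid metabolism (15 of 19 lower, median −0.32) and tight junction and adhesion genes (11 of 13 lower, median −0.64) were called at adjusted p of 0.0032, 0.0212, 0.02 and 0.0251, with adjusted p of 0.867, 0.909, 0.867 and 0.909 with an estimated correlation. Examples are the desmosomal cadherin Dsg1a (−1.42 ± 0.58), the transglutaminase Tgm5 (−2.05 ± 0.36, the only member of these 4 lists to pass in edgeR adjusted over its list alone), Sptlc3 of sphingolipid synthesis (−1.89 ± 0.64) and occludin (Ocln, −1.08 ± 0.41). Sprr2d of the cornified envelope list was higher, at 4.26 ± 1.20. Over all genes edgeR called 0 members of the 4 lists, and DESeq2 called 1 higher and 1 lower of the cornified envelope and 1 lower of barrier lipid metabolism. Leaving out control 3 ended these 4 calls (adjusted p of 0.0616, 0.135, 0.109 and 0.281), and so did leaving out osimertinib 3 for suprabasal differentiation (0.0528), cornified envelope (median −0.25, 0.444) and tight junction genes (0.226), control 1 for barrier lipid (median −0.22, 0.161) and tight junction genes (0.118), and control 2 for the cornified envelope (0.0701). Without osimertinib 1 the cornified envelope median was −1.50, without control 2 the barrier lipid median was −0.49, with quantile normalization it was −0.50, and without control 3 the tight junction median was −0.38. With the skeletal muscle score as a covariate the medians were −0.89, −0.69, −0.32 and −0.35 and no call was left (adjusted p of 0.0724, 0.156, 0.153 and 0.271). With that covariate and control 3 left out, suprabasal differentiation (median −0.98, adjusted p = 0.0304), barrier lipid (−0.38, 0.0313) and tight junction genes (−0.48, 0.00615) passed, and the cornified envelope did not (−0.55, 0.289).

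Of 15 stress and wound keratinocyte genes 12 were higher (median 1.37, adjusted p = 0.00346 by camera, and adjusted p = 0.858 with an estimated correlation), and 2 passed in edgeR adjusted over the list alone, against 0 in edgeR and 4 in DESeq2 over all genes. The 2 were Sprr2h (2.34 ± 0.47) and Krt17 (1.36 ± 0.32), a keratin of wounded epidermis that the follicle also makes. Krt6a, another wound keratin, was lower in each treated sample than in each control (−0.93 ± 0.42). With the muscle score as a covariate and control 3 left out, the list median was 3.14. The alarmins S100a8 and S100a9 averaged 7.27 ± 6.30 and 5.42 ± 4.81 CPM in controls and 126 ± 114 and 147 ± 138 CPM in treated skin. S100a8 was at 254 CPM in osimertinib 3, where Krt10 was at 169 CPM against 742 to 3152 in the other libraries.

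The immune lists that camera called went both ways, and others were not called. Among the latter were macrophages and monocytes (adjusted p = 0.192 by camera), complement (0.153) and dendritic and Langerhans cells (0.649). MHC class II presentation (0.767), chemokines (0.743) and mast cells and basophils (0.92) were not called either. Of 21 interferon-response genes 20 were lower, with a median log2 fold change of −1.06 (adjusted p = 8.38e-09 by camera, and adjusted p = 0.664 with an estimated correlation), or −0.71 without control 3, −0.63 with limma on log2(FPKM + 1) and −0.66 with the muscle covariate and control 3 left out, and 3 passed in edgeR adjusted over the list alone, against 0 in edgeR and 5 in DESeq2 over all genes. Those 3 included Ifi27l2a (−2.01 ± 0.47) and the RNA sensor Ifih1 (−1.05 ± 0.27). MHC class I presentation was lower in 14 of 15 genes (median −0.66, adjusted p = 0.000354, and adjusted p = 0.867 with an estimated correlation), with B2m at −0.89 ± 0.35. T cell and NK cell genes were lower in 9 of 11 (median −1.38, adjusted p = 0.0212, and adjusted p = 0.869 with an estimated correlation), as in Cd3g (−1.57 ± 0.53), and type 2 cytokine response genes in 10 of 13 (median −0.37, adjusted p = 0.0459, and adjusted p = 0.867 with an estimated correlation), led by Arg1 and Retnla (−1.82 ± 0.49). Neutrophil genes were higher in 4 of 5 (median 3.64, adjusted p = 0.0418, and adjusted p = 0.664 with an estimated correlation), with the receptor Clec4d at 3.64 ± 1.07. Only 5 of the 15 neutrophil genes listed, and 11 of the 27 T cell and NK cell genes, were matched and passed the filter on mean FPKM. That mean is over both groups, so a gene high in 1 group passes more easily. The T cell call was lost without control 3 (median −0.80, adjusted p = 0.201) or osimertinib 2 (0.139), and with no filter on low values (median −0.54, 0.111). The type 2 call was lost without control 1 (median −0.31, 0.127), control 3 (−0.27, 0.122) or osimertinib 2 (−0.32, 0.209). It was also lost with quantile normalization (−0.34, 0.0746) and with hair and muscle genes removed (0.0539), although the median stayed at −0.37 in the latter. The neutrophil call was lost without control 2 (0.137) or osimertinib 1 (0.0913) and with a mean FPKM of at least 5 (0.242), and its median was 2.27 without osimertinib 3. With the muscle score as a covariate the T cell, type 2 and neutrophil medians were −0.88, −0.28 and 3.95 and none passed (adjusted p of 0.183, 0.153 and 0.0579). With that covariate and control 3 left out they were −0.77, −0.27 and 5.11, and the neutrophil list passed (adjusted p = 0.00222) while the T cell and type 2 lists did not (0.159 and 0.082). With limma on log2(FPKM + 1) the T cell, type 2 and neutrophil medians were −0.63, −0.22 and 1.66. With quantile normalization the T cell and neutrophil medians were −0.86 and 1.48, and with a mean FPKM of at least 5 the type 2 median was −0.60.

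Targets of the glucocorticoid receptor and nerve sheath genes were lower. In the glucocorticoid-response list 11 of 13 genes were lower (median −0.70, adjusted p = 0.00225 by camera, and adjusted p = 0.664 with an estimated correlation), and 3 lower and 1 higher passed in edgeR adjusted over the list alone, against 0 over all genes, where DESeq2 called 3 lower and 1 higher. Fkbp5, a co-chaperone of the receptor, was at 139 ± 6.22 CPM in controls and 42.2 ± 11.5 CPM in treated skin (−1.73 ± 0.23), Tsc22d3 differed by −1.81 ± 0.25 and Zbtb16 by −1.71 ± 0.31. Lcn2, an iron-binding protein also made in inflammation, was higher by 3.34 ± 0.76. Of 11 Schwann cell and nerve genes 10 were lower (median −0.65, adjusted p = 0.00121, and adjusted p = 0.664 with an estimated correlation), and Mal (−1.27 ± 0.29) and the myelin protein Mbp (−1.14 ± 0.29) passed in edgeR adjusted over the list alone, against 0 in edgeR and 3 in DESeq2 over all genes. The median of this list was −1.14 with a mean FPKM of at least 5 and −0.34 with limma on log2(FPKM + 1).

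**Figure D3:**
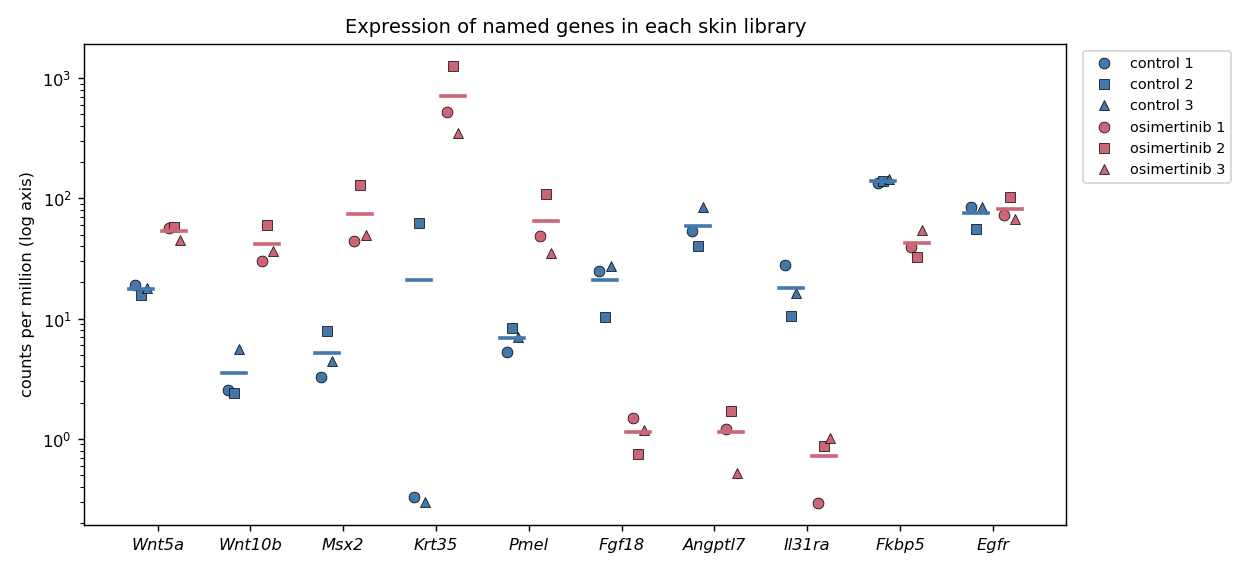
Points give TMM-scaled CPM on a log axis for 10 genes in each of 3 control (blue) and 3 osimertinib (red) libraries, and horizontal bars the group means. Fgf18 lies between 10.2 and 27.5 in controls and between 0.748 and 1.48 in treated skin, and Egfr overlaps between the groups, at 55.8 to 84.7 and 67.2 to 103.

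Over all 13498 genes tested, edgeR called 0 at an adjusted p under 0.05 (smallest adjusted p 0.0621). At an unadjusted p under 0.05 there were 1883 genes, 975 higher and 908 lower, where 5% of the genes tested is 675. This number was 899 without control 1, 2989 without control 2 and 1048 without osimertinib 2. When the 6 libraries were split 3 against 3 in other ways, it ran from 75 to 1309. The 675 is thus no bound on what another grouping gives. DESeq2 called 858 genes, 460 higher and 398 lower, with 62 adjusted p not given, and limma on log2(FPKM + 1) called 17, 12 higher and 5 lower, all 17 also called by DESeq2. Unadjusted, limma on the deposited FPKM values gave 903 higher and 376 lower, and the median log2 fold change of all genes was −0.05 in edgeR with TMM and 0.07 in that limma fit, which differ in model as well as in scaling. All 3 treated samples lay above all 3 controls in 1532 genes (11.3%) and below them in 1266 (9.38%), where chance gives 5% each on average. Since genes vary together, 1 grouping can depart from that average by chance.

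The 10 genes with the smallest p among those higher did not pass (adjusted p of 0.0969 to 0.13 in edgeR), and all had separated groups. Besides Wnt5a and Wnt10b they included Lbh (log2 fold change 1.41 ± 0.14, SE), the limb and heart transcriptional cofactor, Irx4 (2.34 ± 0.26), the growth factor midkine (Mdk, 3.15 ± 0.35), the linker histone H1f10 (2.16 ± 0.26), Wfdc18 (4.28 ± 0.58), the ETS factor Etv4 (2.38 ± 0.33), and Nckap5l (2.50 ± 0.34). Wfdc18 differed by 2.20 with limma on log2(FPKM + 1) and by 1.94 with quantile normalization, and Nckap5l by 1.66 with the latter. All 10 were called by DESeq2. Mdk averaged 1.89 ± 0.72 CPM in controls and 16.8 ± 2.91 CPM in treated skin.

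The 10 genes with the smallest p among those lower did not pass either (adjusted p of 0.0867 to 0.112 in edgeR), had separated groups and were all called by DESeq2. Serpinb11, a serpin family member (chromosome 1, 107361198 to 107380475), averaged 50.4 ± 10.4 CPM in controls and 5.30 ± 1.26 in treated skin, 9.51-fold lower. Angptl7, a secreted angiopoietin-like protein (chromosome 4, 148495183 to 148500460), averaged 59.3 ± 23 and 1.14 ± 0.59 CPM, 51.9-fold lower. Arginase 1 (Arg1) was 17.9-fold lower, with a log2 fold change of −4.16 ± 0.51 (SE). The others besides Fgf18 were Ralgps1 (−2.26 ± 0.22), the adenylate cyclase Adcy1 (−3.27 ± 0.33), Wfdc3 (−3.66 ± 0.39), the estrogen sulfotransferase Sult1e1 (−3.07 ± 0.36), the anion channel Best2 (−3.72 ± 0.44) and the aldehyde dehydrogenase Aldh1a7 (−2.05 ± 0.25). With limma on log2(FPKM + 1) the log2 fold changes of Ralgps1, Adcy1, Sult1e1 and Best2 were −0.96, −1.74, −1.68 and −1.36, and with quantile normalization −1.16, −1.96, −1.94 and −1.49. That of Angptl7 was −5.70 ± 0.57 in edgeR and −3.97 with limma on log2(FPKM + 1).

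None of 10 genes of the EGFR family passed in edgeR, DESeq2 or limma. Egfr, the target of the drug (chromosome 11, 16752203 to 16918158), averaged 75.0 ± 16.6 CPM in controls and 81.0 ± 19.0 CPM in treated skin (adjusted p = 0.919 in edgeR). The related receptors Erbb2 and Erbb3 differed by −0.26 ± 0.38 and −0.72 ± 0.38 on the log2 scale (SE). Erbb3 was at −0.27 without control 3, −0.28 with the muscle covariate, −0.40 with that covariate and control 3 left out, and −0.48 with limma on log2(FPKM + 1). Among ligands, Btc differed by −2.29 ± 0.97 (adjusted p = 0.367), Tgfa by −0.31 ± 0.31, Egf by 0.10 ± 1.06, Areg by 0.20 ± 0.73, Ereg by −0.47 ± 0.95, Hbegf by −0.15 ± 0.68 and Epgn by 0.33 ± 0.98. The sign for Hbegf turned with limma on FPKM, and those for Egfr, Erbb2, Egf, Areg, Ereg, Hbegf and Epgn turned in at least 1 fit with a library left out. Btc and Tgfa kept their sign. Btc was at −3.75 without osimertinib 1, −1.21 with limma on log2(FPKM + 1) and −1.30 with quantile normalization. Tgfa was at −0.57 without control 2, −0.15 without control 1, −0.14 without control 3, −0.11 with the muscle covariate, −0.20 with quantile normalization, and −0.14 to −0.15 with limma on FPKM. Camera did not call the list of 12 EGFR family genes and ligands (median −0.21, adjusted p = 0.285), nor 16 ERK feedback targets (median 0.13, adjusted p = 0.285), 14 immediate early genes, all lower (median −0.80, adjusted p = 0.093), 13 antimicrobial peptides (median 0.98, adjusted p = 0.17) or 10 genes of the IL-17 and IL-23 axis (median 0.96, adjusted p = 0.1). In edgeR adjusted over the list alone, 1 ERK target passed as higher, and 2 antimicrobial peptides as higher and 1 as lower. Over all genes DESeq2 called 1 ERK target higher, 4 antimicrobial peptides higher and 1 lower, and 2 IL-17 axis genes higher. Fry for change in either direction called the ERK (adjusted p = 0.0286) and antimicrobial lists (adjusted p = 0.0228).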

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

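The use of limma on log2(FPKM + 1) beside the count test, and the muscle covariates, were added after the data were seen. The design had named that limma test for a table without raw counts. The other settings were planned. The count of genes called by edgeR, 0, stayed at 0 under the remaining settings, among them each leave-one-out fit, and became 858 with DESeq2 (460 higher, 398 lower), 17 with limma on log2(FPKM + 1) (12 and 5), 2 with limma at a pseudocount of 0.1 (1 and 1), 1 at 0.01 (0 and 1), 2 with a mean FPKM of at least 5 (0 and 2), 20 with quantile normalization and limma (11 and 9), 1 with no trend in moderation (0 and 1) and 1 with the muscle covariate (0 and 1); the causes were not tested. The number at an unadjusted p under 0.05, 1883, was 2987 with no filter, which tests more genes, 896 with a mean FPKM of at least 5, which tests fewer, and 899 to 2989 with a library left out. Of 22 lists called, 13 were called in every setting that could test them except with an estimated correlation (0 called) and with fry for a common direction (0 called); fry for change in either direction called 15 of 53, and leaving out a library gave 19 to 29. The skeletal muscle list reversed its camera direction without control 3, which held few muscle transcripts (median −0.91). It also reversed with the muscle covariate (median −0.13) and with that covariate and control 3 left out (−0.13). That covariate is the score of this same list, so the fits with it cannot show how the list differs between groups. With a library left out the median ran from −0.91 to 1.42. The 20 leading genes kept their direction in every setting that tested them, though not their size. They had been picked for a small p in these data and had separated groups. Leaving out a library could therefore hardly turn their direction, and the kept direction is no separate evidence. EGFR family genes near 0 changed sign, and the cause was not tested: with a library left out, Egfr ran from −0.0944 to 0.26, Erbb2 from −0.56 to 0.0367, Egf from −0.48 to 1.64, Areg from −0.60 to 0.67, Ereg from −1.95 to 0.30, Hbegf from −0.77 to 0.43 and Epgn from −0.86 to 0.91. Erbb2 was 0.0636 with the muscle covariate, and Hbegf was 0.025, 0.0769 and 0.0841 with limma at pseudocounts 1, 0.1 and 0.01, 0.50 with the muscle covariate, 0.44 with that and control 3 left out, and 0.0161 with the replicate block. Samples with the same replicate number did not all deviate together (r across genes of 0.22, 0.03 and −0.11 for numbers 1, 2 and 3). The 0.22 was the highest r of any control with any treated sample, but not every sample correlated best with its own number. The fit with a replicate block called 0 genes, 1530 at an unadjusted p under 0.05 (750 lower), and 25 lists. Library weights gave control 1 a weight of 317, against 0.0738 to 1.02 for the others, and no fit was made with them. The spread between libraries limited calls more than depth, since on simulated counts with a dispersion of 0.02 at these library sizes edgeR recovered 98.5% of genes changed 2-fold, against 0% with the spread of these libraries.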

Other observations

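Among KEGG pathways, which were tested after the data had been seen, camera called 30 of 296. DNA replication was higher with a median log2 fold change of 0.64 over 35 genes (adjusted p = 3.51e-12 by limma's camera), followed by the spliceosome (0.24 over 128 genes, adjusted p = 2.16e-07), ribosome biogenesis (0.27 over 70 genes, adjusted p = 8.14e-06), RNA transport (0.20 over 145 genes, adjusted p = 1.12e-05) and the cell cycle (0.23 over 110 genes, adjusted p = 1.96e-05). Steroid hormone biosynthesis was lower (−0.70 over 22 genes, adjusted p = 0.0191), as were sphingolipid metabolism (−0.33 over 40 genes, adjusted p = 0.0183) and endocytosis (−0.14 over 218 genes, adjusted p = 0.0081). These lower pathways were not picked by rank. The lower pathway with the smallest p was autoimmune thyroid disease (−0.64 over 21 genes, adjusted p = 0.000838 by camera). With an estimated correlation none of the 296 was called, the adjusted p of each pathway named here being 0.954.

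Some genes outside the naming rule, chosen after their values were seen, had separated groups. Il31ra, a receptor subunit for the itch cytokine IL-31, averaged 18.1 ± 8.75 CPM in controls and 0.725 ± 0.381 CPM in treated skin, 24.9-fold lower (n = 3 per group, adjusted p = 0.13 in edgeR). Limma on log2(FPKM + 1) called Mycn, a growth-promoting transcription factor, at 1.46 ± 1.44 and 25.9 ± 7.97 CPM (adjusted p = 0.0414 in limma, 0.18 in edgeR). It also called Lrrc15, a membrane protein, at 4.29 ± 3.71 and 75.8 ± 29.0 CPM (adjusted p = 0.0453 in limma, 0.19 in edgeR), and Aldh1a3, which makes retinoic acid, at 2.63 ± 1.59 and 23.2 ± 3.91 CPM (adjusted p = 0.0414 in limma, 0.179 in edgeR).

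The tests below on DESeq2 calls, on KEGG pathways, on single libraries and phase in the hair pattern, and on muscle in control 3 were chosen after the result was seen. The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. With edgeR the real split called 0 genes and the highest other 0, so that all 10 gave as many. DESeq2 called 858 in the real split and 312 in the highest other (controls 1 and 3 with osimertinib 1), and 1 of 10 splits, the real one, gave as many. Camera called 22 lists in the real split and 28 in the highest other, with 5 of 10 giving as many. For KEGG pathways the numbers were 30 and 102, with 8 of 10 giving as many. A structure of the samples other than the groups could give this, and so could the correlation preset in camera. With an estimated correlation the real split called 0 pathways, and the other splits were not run that way, so the cause stays open. The pathways named above had been picked for a small p in the real split. Counting that split, as small a p came in 4 of 10 splits for autoimmune thyroid disease and 3 of 10 for sphingolipid metabolism. For endocytosis, ribosome biogenesis and the cell cycle it came in 2 of 10, and for the other pathways named in 1 of 10. By chance 1 in 10 of all pathways would have its smallest p in the real split, so this singles out none of them. The real split gave the smallest p of the 10 for 6 of the 22 called lists: hair matrix and follicle growth and melanocytes, both higher, and hair follicle stem cells, Schwann cells and nerve, glucocorticoid response, and Wnt and BMP inhibitors, all lower. The 22 lists had been picked for a small p in this same split, and no list outside them gave this. Over all lists the share is thus 6 of 53, about the 1 in 10 that chance gives. Counting the real split, 2 of 10 splits gave as small a p for keratin-associated proteins, hair shaft keratins, the inner root sheath, proliferation and interferon response. For basal keratinocytes 3 of 10 did.

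For the higher hair lists in treated skin, 2 technical explanations and a difference in hair cycle phase were weighed; an effect of the drug itself stays open and was not tested. Muscle content and scaling as the whole cause are argued against by the median log2 fold change of the hair matrix list, whose lowest value over the scalings and muscle covariates was 1.66. For the same list, a single library as the cause is argued against by a lowest median of 1.53 with a library left out. These 2 tests did not cover the structural hair lists, whose medians fell by more without osimertinib 2, as given above. A hair cycle phase unrelated to the drug stays open: the hair shaft keratin score ranged over 5.38 log2 units among the 3 controls, with control 2 nearest to the treated samples. Control 2 also held the most muscle transcripts and phase itself was not measured, so phase and group cannot be told apart in this design.

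In control 3, 95.8% of the 24 muscle genes lay at least 4-fold under the lowest of the other 5 libraries, with a median of −6.77 on the log2 scale, which is consistent with a skin piece that held almost none of the muscle layer under the skin. A library of low complexity is argued against by its 25046 genes with a count above 0, against a median of 24834 over the 6 libraries. No biological explanation was tested, and the labels name no difference in dissection.

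Dbp, an output gene of the circadian clock, was higher in treated skin (1.9 ± 0.54 on the log2 scale, adjusted p = 0.26 in edgeR) and the core clock gene Arntl lower (−0.99 ± 0.19, adjusted p = 0.188), both with separated groups. A different hour of collection could give this, but of 12 other clock genes only 8 went the way this predicts, between the bounds set for and against it. Of these 8, Nfil3 (−0.91 ± 0.19), Npas2 (−1.77 ± 0.54), Clock (−0.57 ± 0.26) and Ciart (0.85 ± 0.41) had separated groups. Hlf (−1.58 ± 0.57), Tef (−0.24 ± 0.33), Nr1d2 (−0.26 ± 0.25) and Per2 (−0.34 ± 0.43) went against it, with groups that overlapped. The hour and the treatment therefore cannot be told apart here. Muscle content is argued against by the difference between Dbp and Arntl, which was 2.90 without and 2.54 with the muscle score as a covariate. An effect of the drug on the clock stays open and was not tested.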
